A study of Homo sapiens with 16 samples.

How the data were processed

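Open chromatin was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in human CD34+ cells from umbilical cord and in erythroid cells cultured from them. The deposited files are 16 peak lists, with 2 libraries for each of 8 stages separated by cell sorting. Per the labels' protocols, progenitor stages were sorted on IL-3R, CD34 and CD36, and erythroblast stages on glycophorin A, band 3 and alpha 4 integrin. The labels name the stages HSPC (hematopoietic stem and progenitor cells), BFUE and CFUE (burst-forming and colony-forming erythroid progenitors), ProE (proerythroblasts), EBaso and LBaso (early and late basophilic erythroblasts), Poly (polychromatic erythroblasts) and Ortho (orthochromatic erythroblasts). The series design states that sorting was done on replicate sets of cells, and does not say whether equal replicate numbers at different stages come from the same cord blood. The p-values here treat the libraries as independent and concern the spread between these libraries only. In the lists as deposited, erythroblast libraries of the same replicate number deviated together, so these p-values can be too small.

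Per the submitters' processing notes, the tools were Trimmomatic 0.32, MACS2 2.1.1.20160309 and bedtools, and the genome build was hg19 (GRCh37). The sources used here do not give the aligner, the treatment of duplicate reads, any shift of the reads or the read depth of a library. Each list was called on a single library, since every library has its own list with its own peak numbering. The deposited lists give a fold enrichment at the summit as a ratio, −log10 of the p-value, −log10 of the q-value and an integer score for each peak. In the deposited lists the lowest −log10 q lies between 1.31 and 1.47, and the narrowest peak spans 200 bp. Peak lists hold no read counts, so depth is unknown and no counting interval can be given, and the number of peaks per library stands in its place.

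Peaks on chromosomes 1 to 22 and X were used. Overlapping peaks of all 16 lists (at least 1 bp) were merged into regions, and a library counted as calling a region when any of its peaks lay in it. Overlap of 2 peak sets was measured as the Jaccard index, the bp covered by both divided by the bp covered by either. The 6 progenitor libraries (HSPC, BFUE, CFUE) were compared with the 10 erythroblast libraries (ProE, EBaso, LBaso, Poly, Ortho), as the protocols divide them. Regions called in 4 to 12 of the 16 libraries were tested with a two-sided Fisher's exact test on called against not called, with Benjamini-Hochberg adjustment at 0.05. A region called in 3 libraries cannot go below an unadjusted p of 0.0357. Class means were compared by exact permutation over all 8008 splits, two-sided. Same-stage overlap was set against all 40320 pairings of replicate 1 with replicate 2 libraries in a one-sided exact test. Correlations across 16 libraries used 100000 permutations, and those across 8 libraries were exact. For adjacent stages, regions called in both libraries of a stage and neither of its neighbor were counted, with no test, since 2 libraries against 2 allow only 3 splits. The named regions are the 5 per direction with the smallest p, ties broken by the mean percentile of fold enrichment within the lists that call them and then by position.

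The comparisons, named-region rule and main alternatives were fixed before the data were examined. The alternatives were lists of equal length (the 30362 peaks with the highest −log10 p in every library), a −log10 q of at least 5, at least 50% of a region covered, no filter on regions, a replicate block, the overlap coefficient, leaving out the HSPC libraries, and leaving out each library in turn. Genes, promoters and motifs were not analysed here, since no gene annotation or sequence of hg19 was used. The gene table at hand follows another assembly, so it served only to count protein-coding genes per chromosome. Genes per Mb are these counts divided by the largest peak end on the chromosome, which includes any stretch before the first peak.

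Calculations used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and merging and Jaccard values were checked against bedtools 2.31.1. The region test was tested on simulated calls for the progenitor and erythroblast comparison, built on the 56485 tested regions with the calling rate of each library. Calls were drawn independently for each library. In the real lists, erythroblast libraries of the same replicate number deviated together, at correlations of 0.147 to 0.44 between stages. The simulated rates therefore hold for independent libraries and do not measure the error of the test on these lists. With no changed region the test made 0 calls. With 20000 changed regions called at rates of 0.9 and 0.1 it recovered 81.9% of them, and 1.28% of its calls were wrong. At rates of 0.75 and 0.25 it recovered 0.93%. With only 200 changed regions it recovered 0 of them at either pair of rates. The smallest p that 6 against 10 libraries allow is 0.000125, and too few of the 200 regions reached it to pass the adjustment.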

Results

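The series followed open chromatin through human erythroid development, from cord blood CD34+ cells through the BFUE and CFUE progenitors to the terminal erythroblast stages, with 2 ATAC-seq libraries at each of 8 stages. The number of peaks per library ranged from 30362 in Ortho replicate 1 to 79805 in HSPC replicate 2. Numbers inside the deposited peak names fall into 4 separate sets of libraries: HSPC, BFUE with CFUE, erythroblasts of replicate 1, and erythroblasts of replicate 2. None of these sets holds libraries of both classes, so in every comparison of progenitors with erythroblasts the library set and the class cannot be told apart. HSPC is a set of its own, so the same holds for HSPC against any other stage, and for the step from CFUE to ProE. The HSPC cells were also uncultured, unlike the later stages, so culture cannot be told apart from stage in comparisons with HSPC.

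The number of peaks at each stage was compared first. Peak number also moves with read depth, which is unknown here, so it does not measure the amount of open chromatin by itself. HSPC had the most peaks, 77687.5 ± 2994.6 (SD, n = 2), covering 31.9 Mb ± 2.92 of the genome. BFUE, CFUE and ProE had 58325 ± 22913, 57521.5 ± 26999.5 and 57859.5 ± 25706.9 peaks (SD, n = 2 each). The polychromatic and orthochromatic erythroblasts, whose nuclei condense before they are expelled, had 40409.5 ± 9718 and 41653.5 ± 15968.6 peaks. Replicates of a stage differed widely: ProE had 39682 peaks in replicate 1 and 76037 in replicate 2, and CFUE had 76613 in replicate 1 and 38430 in replicate 2. The 6 progenitor libraries averaged 64511 ± 18891 peaks (SD) and the 10 erythroblast libraries 49197 ± 16142 (SD), a difference of -15314.5 that did not pass the exact permutation test (p = 0.105). Leaving out BFUE replicate 1, CFUE replicate 2 or ProE replicate 2 brought that p to 0.0453, 0.035 and 0.0486 by the same exact test, while the difference shrank to -8660 (exact p = 0.299) with a −log10 q of at least 5 and to -8726 (exact p = 0.381) without the HSPC libraries. Peak number fell with stage order over the 16 libraries (Pearson r = -0.559, permutation p = 0.0272, adjusted 0.0645; Spearman rho = -0.58, permutation p = 0.0209, adjusted 0.0418 over the 4 relations computed). Without the HSPC libraries, and with the replicate numbers pooled, r was -0.39 (permutation p = 0.165), so the pooled relation rests on those libraries. Within replicate 1 the exact permutation test gave rho = -0.905 (n = 8, p = 0.00456, adjusted 0.0183), and within replicate 2 rho = -0.571 (n = 8, exact p = 0.151). Without HSPC, a fit added after the values were seen, rho was -0.929 in replicate 1 (n = 7, exact p = 0.00675, adjusted 0.0135) and -0.357 in replicate 2 (n = 7, exact p = 0.444). Libraries of a replicate number come from several library sets, so none of these fits separates stage from set. In replicate 1 every erythroblast list (30362 to 39682 peaks) was shorter than every progenitor list (42123 to 76613 peaks).

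**Figure D1:**
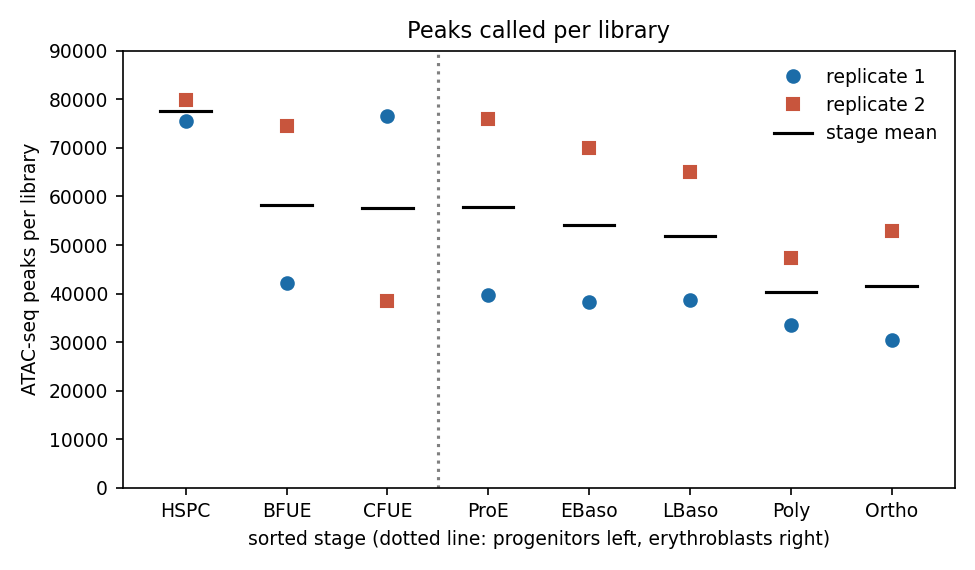
ATAC-seq peaks per library (vertical axis) at each sorted stage (horizontal axis), with circles for replicate 1, squares for replicate 2 and a bar for the stage mean. HSPC libraries hold 75570 and 79805 peaks, and each erythroblast stage has more peaks in replicate 2 than in replicate 1.

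Whether cells sorted as the same stage share open chromatin was asked from the overlap of peak sets. Libraries of the same stage overlapped more than libraries of different stages: the mean Jaccard index was 0.486 ± 0.0524 (SD) over the 8 same-stage pairs and 0.36 ± 0.0943 (SD) over the 56 pairs of replicate 1 with replicate 2 libraries of different stages (exact pairing test, one-sided p = 0.00057). With lists of equal length these values were 0.583 and 0.401 (exact p = 0.000174), and 5 of the 8 replicate 1 libraries were closest to their own stage, against 3 of 8 in the lists as deposited. With pairings kept within the class, a test added after the values were seen, the one-sided exact p was 0.0153 in the lists as deposited and 0.00972 in lists of equal length. Neither pairing test separates stage from library set among the progenitors, since HSPC forms a set and BFUE with CFUE another. Among the 5 erythroblast stages alone, whose same-stage pairs lie across library sets, same-stage overlap did not pass (exact p = 0.0583 in either kind of list). The 3 progenitor stages allow no p below 0.167. On average HSPC shared least with the erythroblasts, at a mean Jaccard index of 0.27 ± 0.0105 (SD, 20 pairs) in lists of equal length, followed by BFUE at 0.29 ± 0.0247 and CFUE at 0.395 ± 0.055. The pairs share libraries, and the ranges of HSPC (0.256 to 0.289) and BFUE (0.241 to 0.323) overlapped. With erythroblasts of replicate 2, BFUE replicate 1 shared less than either HSPC library at every stage, so the order of HSPC and BFUE was not uniform. CFUE stood between BFUE and ProE, with mean Jaccard indices of 0.43 to BFUE and 0.431 to ProE in lists of equal length (4 pairs each). ProE, EBaso and LBaso were close to each other, with Jaccard indices of 0.67 and 0.769 between ProE and EBaso and 0.698 and 0.766 between EBaso and LBaso in replicates 1 and 2. LBaso and Poly were less alike, at 0.546 and 0.639. Among erythroblasts, adjacent stages of the same replicate number overlapped more (0.681 ± 0.0733, SD, 8 pairs) than the same stage of different replicate numbers (0.588 ± 0.0264, SD, 5 pairs), also in lists of equal length. Adjacent stages of different replicate numbers reached 0.578 ± 0.0412 (SD, 8 pairs), close to the same-stage value.

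**Figure D2:**
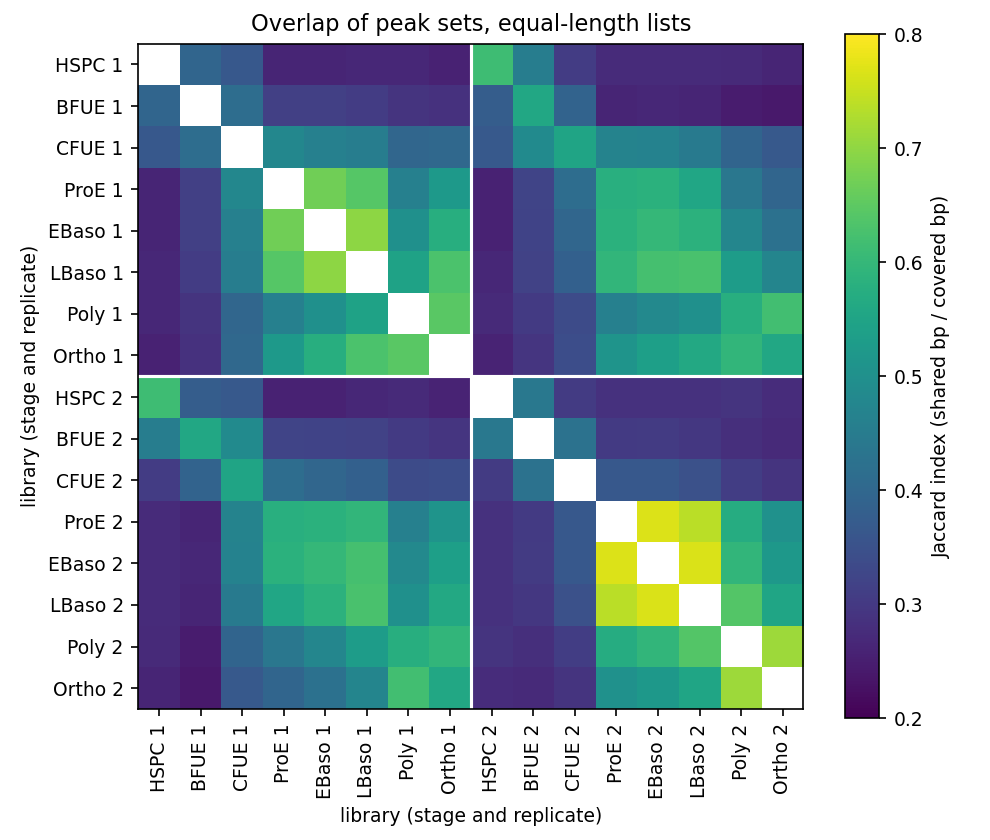
Jaccard index of peak sets (color, shared bp over covered bp) for every pair of the 16 libraries, from lists of 30362 peaks each, ordered by stage within replicate 1 and then replicate 2 on both axes. The erythroblast libraries of replicate 2 form the brightest block, reaching 0.769 between ProE and EBaso, and HSPC and BFUE are the darkest against erythroblasts.

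The passage from progenitors to erythroblasts was compared region by region. Of 162065 merged regions, covering 69.9 Mb, 11478 were called in all 16 libraries and 43035 in a single library. Among 56485 regions tested, 20991 differed between the classes by Fisher's exact test with Benjamini-Hochberg adjustment, 15420 of them called more often in progenitors and 5571 more often in erythroblasts. With lists of equal length 15042 regions differed, 7664 called more often in progenitors and 7378 in erythroblasts, so the share called more often in erythroblasts was 26.5% in the lists as deposited and 49% in lists of equal length. Of the regions higher in erythroblasts 3515 (63.1%) were called the same way in lists of equal length, of those higher in progenitors 5564 (36.1%), and 0 went the opposite way. The balance also turned with the erythroblast libraries used: with those of replicate 2 alone, 9887 regions were higher in erythroblasts and 6961 in progenitors in the lists as deposited. Complete separation was common: 2311 regions were called in all 6 progenitor and no erythroblast libraries, and 554 in all 10 erythroblast and no progenitor libraries. Together these are 2865 regions, against a median of 0 and at most 257 in 99 other splits of the libraries into 6 and 10. With lists of equal length the counts were 1494 for progenitors and 1578 for erythroblasts, so the progenitor excess was absent. The total depends on the early progenitors: 10986 or 10956 regions differed without HSPC replicate 1 or 2, 12442 or 10447 without BFUE replicate 1 or 2, and 4886 without both HSPC libraries.

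The regions named here were called in all libraries of their class and none of the other, each at an adjusted p of 0.00246 by Fisher's exact test, with positions on hg19. The erythroblast region with the highest fold enrichment within its lists lay on chromosome 8 at 97923620 to 97924469, at a mean percentile of 96.6. The others were on chromosome 2 at 75518753 to 75519281, chromosome 11 at 113551826 to 113552420, chromosome 12 at 51295379 to 51296078 and chromosome 6 at 36231267 to 36231832. The leading progenitor region lay on chromosome 3 at 190701471 to 190702145, at a mean percentile of 99.7. It was followed by chromosome 4 at 167261530 to 167262092, chromosome 7 at 126341041 to 126341713, chromosome 4 at 183890857 to 183891483 and chromosome 18 at 59932148 to 59932658.

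The direction of change differed between chromosomes, a feature examined after the values were seen. On chromosome 19, 349 of 400 changed regions (87.2%) were called more often in erythroblasts, on chromosome 22 it was 175 of 193 (90.7%) and on chromosome 17 it was 281 of 413 (68%). On chromosomes 4, 13 and 18 the shares were 12.7%, 15% and 15.7%. With lists of equal length the shares on chromosomes 19, 22 and 17 were 98.2%, 98.2% and 92.6%, and those on chromosomes 4, 13 and 18 were 23.7%, 25.5% and 25.1%.

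**Figure D3:**
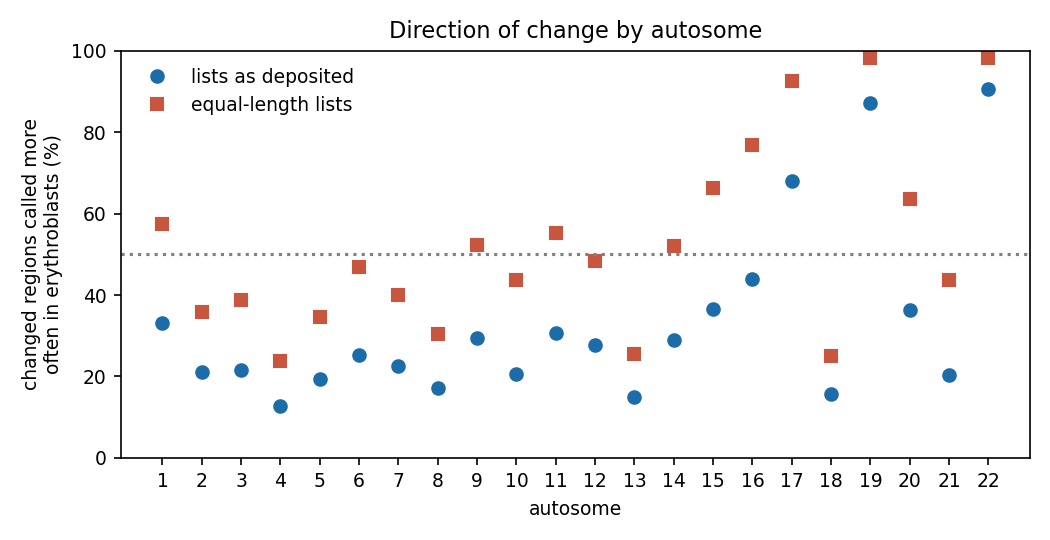
Percent of changed regions that were called more often in erythroblasts (vertical axis) on each of the 22 autosomes (horizontal axis), with circles for lists as deposited, squares for lists of equal length and a dotted line at 50%. Chromosomes 17, 19 and 22 lie above the line in both kinds of list, and chromosomes 4, 13 and 18 lie below it in both.

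The steps of differentiation were compared through regions called in both libraries of a stage and neither library of its neighbor. The largest turnover was among progenitors and at the entry into the erythroblast series. The steps from HSPC to BFUE and from CFUE to ProE also cross library sets. From HSPC to BFUE 14460 regions were lost and 3590 gained, from BFUE to CFUE 6931 were lost and 4642 gained, and from CFUE to ProE 5606 were lost and 4042 gained. The early erythroblast steps separated few regions: 637 lost and 154 gained from ProE to EBaso, and 521 lost and 246 gained from EBaso to LBaso. A further change came from LBaso to Poly, with 4675 regions lost and 1728 gained. From Poly to Ortho 210 were lost and 185 gained. Loss and gain were closer to balance with lists of equal length: 5086 regions were lost and 4384 gained from HSPC to BFUE. The counts were 5443 and 5585 from CFUE to ProE, and 2960 and 2778 from LBaso to Poly. Equal lengths draw loss and gain together whatever the source of an imbalance. They therefore do not show whether list length or a real net loss shaped the deposited counts.

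With 2 libraries per stage the other groupings of the same 4 libraries serve as the comparison. From HSPC to BFUE the stages separated 18050 regions, while grouping by replicate number separated 3838 and crossing the replicates 2809. From LBaso to Poly the stages separated 6403 regions in the lists as deposited, fewer than the 6790 separated by replicate number, and in lists of equal length 5738, against 1532 by replicate number and 535 crossed. From BFUE to CFUE the stages separated 11573 regions in the lists as deposited and the crossed grouping 10253. From CFUE to ProE the stages separated 9648, fewer than the 11078 of the crossed grouping, which joins the longer lists of these stages. With lists of equal length the stages separated 9824 and 11028 regions at these steps, and neither other grouping exceeded 1303. Between ProE and EBaso and between EBaso and LBaso, grouping by replicate number separated more regions than the stages did, 3090 against 1115 and 2853 against 1174 in lists of equal length. Poly and Ortho differed from the other steps: Poly replicate 1 with Ortho replicate 2, set against Poly replicate 2 with Ortho replicate 1, separated 3052 regions in lists of equal length, and the stages as labelled separated 495.

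**Figure D4:**
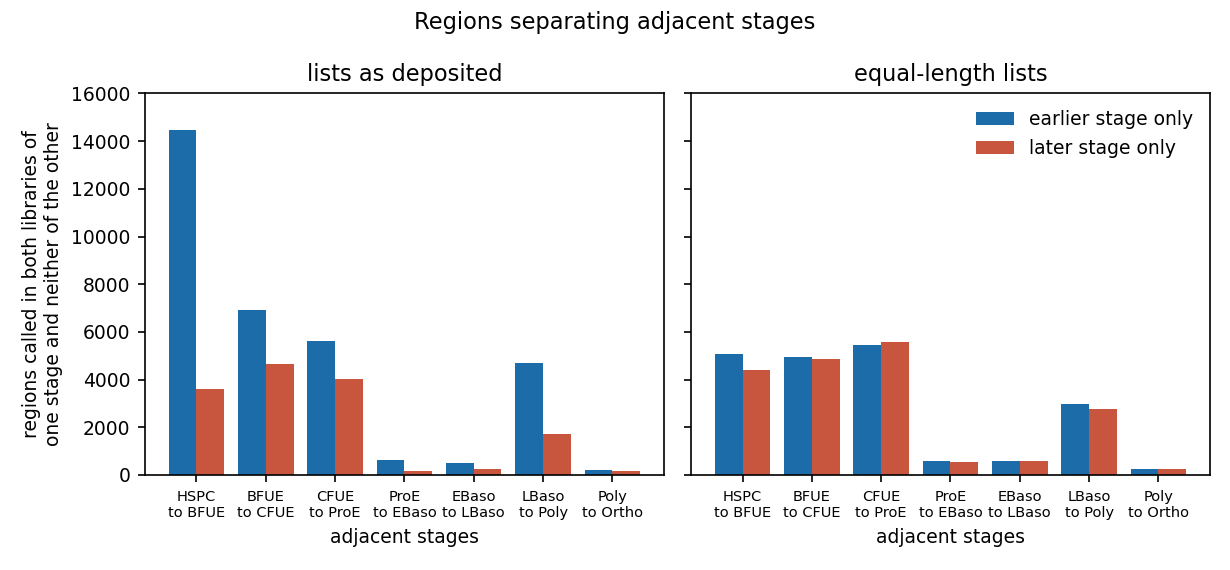
Regions called in both libraries of a stage and neither library of the adjacent stage (vertical axis) for the 7 steps (horizontal axis), with blue bars for regions of the earlier stage and red bars for regions of the later stage, in lists as deposited and in lists of equal length. The steps up to ProE and the step from LBaso to Poly are the tall ones in both panels.

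Regions confined to a single stage were sought next. HSPC had 9743 regions called in both of its libraries and no other library, BFUE had 1596 and CFUE 469. ProE had 83, EBaso 15, LBaso 23, Poly 8 and Ortho 27. HSPC is a library set of its own, so its count cannot be told apart from that of its set. The libraries of each erythroblast stage lie in different sets, so the counts of progenitor and erythroblast stages are not directly comparable. Pairs of libraries from different stages shared a median of 11.5 such regions. The highest value was 1831, for ProE and EBaso of replicate 2, which belong to the same library set. With lists of equal length HSPC had 3685, BFUE 1477 and CFUE 767, while ProE had 147, EBaso 27, LBaso 38, Poly 60 and Ortho 98. The highest pair from different stages was then Poly replicate 1 with Ortho replicate 2 at 882.

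Most regions that changed state did so at a single step. In lists of equal length 24893 regions were either called in both libraries or in neither at every stage, and 30.3% of them were called at all 8 stages. Loss at a single step accounted for 7799 regions and gain at a single step for 4623. A further 4238 were gained and later lost, among them 535 called at ProE, EBaso and LBaso and at no other stage. Only 462 were lost and regained. The gains held through Ortho numbered 1107 at CFUE, 1578 at ProE and 1097 at Poly. In the lists as deposited 16840 regions were lost at a single step and 2071 gained, with gains held through Ortho of 796 at CFUE, 554 at ProE and 428 at Poly, so the balance of loss and gain and the rank of these steps depend on list length.

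CFUE held parts of the earlier and the later peak sets, and so did BFUE. Of 4712 regions called in every HSPC and BFUE library and no erythroblast library, in lists of equal length, CFUE called 31.7% in both of its libraries and 50.3% in neither. Of 3391 regions called in every erythroblast library and no HSPC or BFUE library, CFUE called 32.6% in both and 46.5% in neither. For BFUE, set between HSPC and all later stages, the shares called in both libraries were 31.9% of 7426 earlier and 26.7% of 2068 later regions, and in the lists as deposited 21.7% of 19050 and 15.1% of 1545. In the lists as deposited the CFUE shares were 24.6% and 44.1% of 9380 regions for the early set, and 33.7% and 23.5% of 2362 regions for the erythroblast set. The CFUE libraries differed in the deposited lists, with replicate 1 calling 75.8% of the erythroblast set and replicate 2 calling 34.5%.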

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

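Among 14 groups of libraries examined for a member far from the others, where chance would give about 0.7, there was 1 such case: the median peak width of Poly replicate 2 was 367 bp, apart from the other 9 erythroblast libraries.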

How the results depend on the processing

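Of 133 alternative values, 99 kept their direction and their side of the threshold or stayed within 1.5 times the value reported. Those with only replicate number 1 or 2 of the erythroblasts, without both CFUE libraries, without Poly and Ortho of replicate 1, on autosomes, or joining equal-length lists with fewer libraries were chosen after seeing the data. The difference in peak number became stronger in some fits that left out a library, over a range of -20530.8 to -12255.8. Same-stage overlap over all 8 stages stayed past its threshold with equal-length lists, stricter lists, the overlap coefficient and pairings within class, and did not pass among the erythroblast stages alone (exact p = 0.0583). With no filter, 8842 regions differed, 6649 higher in progenitors and 2193 in erythroblasts, since more regions entered the adjustment. Without the HSPC libraries 4886 differed, 3581 and 1305, and with equal-length lists 7347, with 3485 higher in progenitors. Equal-length lists gave 7664 regions higher in progenitors. With erythroblasts of replicate 1 alone 13076 differed, 2437 of them higher in erythroblasts, and in equal-length lists 8165, with 3501 higher in progenitors. With those of replicate 2 alone the balance turned, with 9887 higher in erythroblasts and 6961 in progenitors, and in equal-length lists 10690 differed, with 4415 higher in progenitors. Leaving out each library in turn gave 10447 to 20744 regions, 2911 to 5713 higher in erythroblasts and 7367 to 16083 in progenitors. Where an HSPC or BFUE library was left out, the largest p that passed adjustment fell from 0.0114 to 0.00699, which drops a whole step of the coarse exact p-values. Without Poly and Ortho of replicate 1 20737 regions differed. The step from HSPC to BFUE separated 9470 regions in equal-length lists and that from EBaso to LBaso 1174, and the cause was not tested.

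The replicate numbers did not pair progenitors with erythroblasts: deviations of same-numbered libraries correlated at -0.0265 to 0.0427 between stages of different classes and at -0.119 to 0.0253 between progenitor stages. They went together among erythroblast stages, at 0.147 to 0.44 in the lists as deposited and -0.0706 to 0.286 in equal-length lists. With the replicate number as a block 22891 regions differed. The block does not enter the difference in peak number, which is -15314.5 either way, and the exact permutation p within blocks was 0.0749. Promoter, gene locus, gene list and motif analyses with their alternatives were not run, since they need an annotation or sequence of hg19. Read depth is unknown, so a region outside a list is uncalled, not closed.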

Other observations

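The tests of stage order, list length, chromosome shares, the Poly and Ortho libraries and other splits of equal-length lists were chosen only after the results they examine were seen.

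Regions with a clear state at every labelled stage followed the order of differentiation. Each of the 40320 orders of the 8 stages was scored by the number of regions that switch state at a single step, among regions with the same state in both libraries of every stage. The labelled order scored 18911 and no order other than its mirror scored as high, against a median of 1107. In lists of equal length it scored 12422, again the highest, with a median of 1658.5. The 5 erythroblast stages were also ordered from the erythroblast libraries alone, without the progenitors. The labelled order gave 4031 single-switch regions in lists of equal length, the highest of 60 orders when an order and its reverse are taken as the same, and the next, with Poly and Ortho exchanged, gave 3987. In the lists as deposited it gave 3735 and the same next order 3636. These scores keep only regions with the same state in both libraries of each labelled stage, so they take the Poly and Ortho labels as given. The margin over the exchanged order therefore does not decide the order of Poly and Ortho. Within a single replicate number and with lists as deposited, where unequal list lengths enter, 127 of 20160 orders scored at least as high as the labelled order in replicate 1 and 7 in replicate 2, the labelled order included. A candidate explanation for the joint result is that gain and loss of open chromatin within the erythroblast stages follow differentiation.

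Random groupings of the libraries gave fewer changed regions than the classes: of 100 splits into 6 and 10, only 1, the real split, gave as many. The real split is also the one split of these sizes that keeps the 4 library sets whole. Every other split breaks a set up, which may itself lower the count, so the comparison does not measure chance. Nor does it separate the class from the sets. The real split gave 20991, and the highest other 13146, from a split with 5 progenitor libraries in its group of 6. In lists of equal length the real split, again 1 of 100, gave 15042 and the highest other 10530.

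The excess of regions higher in progenitors may come from the longer peak lists of the progenitor libraries. In lists of equal length 49% of changed regions were called more often in erythroblasts, against 26.5% in the lists as deposited. A greater loss than gain of open chromatin on entry into the erythroblast series is therefore not shown by these lists, and a real difference in the amount of open chromatin stays open, since equal lengths would also remove it.

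Erythroblast peaks were placed more often on gene-rich chromosomes. Chromosomes 11, 16, 17, 19 and 22, the 5 autosomes with the most protein-coding genes per Mb, held 13.3% ± 1.27 of autosomal peaks in progenitors (SD, n = 6) and 19.9% ± 1.02 in erythroblasts (SD, n = 10), with all 10 erythroblast libraries above all 6 progenitor libraries (exact permutation p = 0.000125, the smallest these splits can give). By set of libraries the means were 14.4% in HSPC, 12.7% in BFUE and CFUE, 19.1% in erythroblasts of replicate 1 and 20.6% in those of replicate 2. Chromosome 19 held 2.08% ± 0.312 of progenitor and 4.44% ± 0.304 of erythroblast peaks (SD). Across the 22 autosomes gene density correlated with the log2 ratio of the shares (Pearson r = 0.798, permutation p = 4e-05; Spearman rho = 0.92, permutation p = 1e-05, the smallest these permutations can give), and without chromosomes 17 and 19 r was 0.768. Chromosomes of a genome are not independent replicates. After adjustment over the 22 autosomes 10 shares were higher and 10 lower in erythroblasts.

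Longer progenitor lists do not account for this, since the difference was 7.9 percentage points in lists of equal length (exact permutation p = 0.000125) and 6.6 in the lists as deposited. A bias between library sets towards GC-rich sequence, which is common on several of these chromosomes, cannot be told apart from the class. Regions called in all 16 libraries showed a shift of the same sign: those on the gene-rich chromosomes stood 7.48 percentile points of fold enrichment higher, relative to other autosomes, in erythroblasts than in progenitors (exact permutation p = 0.00175). That shift also differed between the erythroblast library sets, with means of 2.27 (0.787 to 4.53) in replicate 1 and 8.17 (6.81 to 9.83) in replicate 2, and replicate 1 overlapped the progenitor libraries, which reached 2.46. Both a bias of the libraries and a wider opening of gene-rich chromatin in erythroblasts could give that shift, and sequence composition itself was not tested.

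The Poly and Ortho libraries of replicate 1 stood in each other's place. LBaso of replicate 1 overlapped Ortho (Jaccard index 0.629, lists of equal length) more than Poly (0.546), while LBaso of replicate 2 overlapped Poly (0.639) more than Ortho (0.553). Poly replicate 1 overlapped Ortho replicate 2 (0.617) more than Poly replicate 2 (0.575), and Ortho replicate 1 overlapped Poly replicate 2 (0.596) more than Ortho replicate 2 (0.559). The crossed grouping of these 4 libraries separated 6.17 times as many regions as the labelled grouping in lists of equal length, where this ratio reached at most 0.659 among the other 27 pairs of stages. In the lists as deposited it was 5.5, and at most 1.15 among the others.

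Unequal lists do not account for this, since it holds in lists of equal length. With each replicate ordered by itself, replicate 2 scored highest of 20160 orders in the labelled order, with 30646 single-switch regions, and replicate 1 scored highest with Poly and Ortho exchanged, with 28355 against 26652 as labelled. The same orders led in lists of 20000 and 10000 peaks, though not in the lists as deposited, and in lists of equal length all 6 pairings of replicates that overlapped better than the labelled pairing exchanged these stages. In the lists as deposited 22 pairings overlapped better, and 19 of them exchanged these stages. Exchanged labels are therefore a candidate explanation, which would have to arise before peak calling, since peak names in all 16 lists carry the labelled stage; the median fold enrichment keeps the labelled order, at 9.35 in Poly and 10 in Ortho of replicate 1 and 8.99 and 9.71 in replicate 2. The share of autosomal peaks on the gene-rich chromosomes keeps it too, in lists of equal length at 19.4% in Poly and 20.5% in Ortho of replicate 1 and 21.9% and 23.1% in replicate 2. Other measures ran in opposite directions in the replicates. From Poly to Ortho the peak number went from 33538 to 30362 in replicate 1 and from 47281 to 52945 in replicate 2. Median peak width went from 322 to 337 bp and from 367 to 340 bp. The gene-rich shift of regions called in all 16 libraries went from 3.11 to 4.53 and from 9.83 to 9.07 percentile points. Sort gates that fell differently in the replicates stay open as untested, and with the exchange the step from Poly to Ortho would separate 3052 regions in place of 495, and that from LBaso to Poly 4748 in place of 5738.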
